A study of Mus musculus with 37 samples.

How the data were processed

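Groups and replicate numbers were taken from the sample labels. The source labels of the knockdown samples number the siRNA 1 or 2 as the library, and whether these are different siRNAs is not stated there. The submitters' processing notes name Bowtie 0.12.9, TopHat2 2.0.6 and Cufflinks 2.2.1 and the genome build mm9. The method and threshold of the DHS calls are not given in the sources used here. Labels and protocol differ on the paternal strain of the 1-cell DNase-seq embryos. By the protocol BDF1 sperm was used for these, while other stages had JF1 sperm and the strain labels of both knockdown series name BDF1 parents. By the protocol the 1-cell embryos also received a higher DNase I concentration than all other samples.

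The deposited DHS lists give chromosome, start and end, and for the 5 stages the authors' annotation class. The definition of the classes is not given in the sources used here. Starts were read as counting from 0, since widths then are round numbers, and are printed with 1 added. The 5 stage lists share coordinates, while the oocyte, sperm and pronuclear lists have coordinates of their own. The authors deposited, for each knockdown, a table of decreased DHSs with a value per library, read here as RPM, and a log2 fold change, per the file headers. The headers do not name RPM, which was inferred from the steps of the deposited values. The deposited log2 fold equals the log2 of mean siControl RPM over mean knockdown RPM with 0.1 added for Nfya and 0.01 for Oct4, to within the rounding of the table. The authors deposited FPKM per gene for the 5 RNA-seq libraries, by the name of the table. No count table was used, and 0 columns of per-sample values were left unused.

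Overlap was at least 1 bp, computed in Python 3.11.15 and tested against bedtools 2.31.1, and compared with 100 shuffles of the regions within their chromosomes, whose lengths were set by the last listed region. Proportions have exact Clopper-Pearson intervals at 95% confidence. Fisher's exact tests were two-sided (scipy 1.17.1), with Benjamini-Hochberg adjustment within each family (statsmodels 0.14.6). Distances to genes and expression of genes near DHSs were planned but not run, because gene coordinates on mm9 were not used here, and the authors' class stands in for position. Tests of class in the decreased lists were added after seeing the data. For lack of gene coordinates no DHS is named by its nearest gene. The planned test of X shares in maternal against paternal pronuclei is not used, because paternal pools hold X-bearing and Y-bearing pronuclei and equal shares are not its no-change value.

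RPM values were whole multiples of the value of 1 read in 100% of cases, with a tolerance of 0.1 reads. Library sizes were taken from those steps. Limma 3.58.1 in R 4.3.3 tested log2(RPM + 0.1), and edgeR 4.0.16 (quasi-likelihood) tested the recovered reads with those library sizes, as an addition made after seeing the data.

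RNA values were tested as log2(FPKM + 1) with limma (eBayes with trend) on the 4 2-cell libraries, with group as the only term, over genes with FPKM of at least 1 in at least 2 libraries and a threshold of adjusted p 0.05. This scale understates changes of low genes. For 20 gene lists written before the data were examined, camera with a preset correlation of 0.01 was used where at least 3 members were measured, with Benjamini-Hochberg adjustment over the 18 lists tested. The cumulus and granulosa list had 2 measured members and the mitochondrial genome list matched 0 genes of the table. The 1-cell library entered definitions and ratios alone. Relative RNA depth came from the most common ratio of values below 0.3 FPKM. Activated genes had a mean siControl FPKM of at least 5 and a ratio of at least 5 over the 1-cell library on the (FPKM + 1) scale, and maternal-high genes a 1-cell FPKM of at least 5 and a ratio of at most the inverse.

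Named genes followed a rule fixed before the data were examined: the NF-Y subunits, the 10 genes each way among those past the threshold with separated libraries, filled by those of smallest p with that separation, from each list that passed and from the 2-cell-stage and maternal oocyte lists the 2 members of highest siControl mean and the 2 of smallest p, from each remaining list the member of highest mean, and the 10 largest ratios each way between 1-cell and 2-cell siControl embryos. In that last comparison genes had at least 5 FPKM in one of the groups.

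The tests were tried on simulated data. For the RNA comparison, 200 of 10533 genes were lowered with the spread of the real libraries. A fall of 1 or 2 on the log2 scale was recovered in 0% of cases and a fall of 4 in 85.9%, with 0 false calls. The lowered genes lay above a set expression level and changed together, so these recoveries are upper estimates for a lone change. With a term for the library number, recovery was 49.4%, 98.7% and 100%, with false shares of 26.9%, 11.0% and 18.6% among calls, above the 5% aimed at. For the Nfya table edgeR recovered 9% of 4-fold and 71.5% of 8-fold falls among 286 sites, and limma 0% and 41%. The simulated sites had the same mean in both siControl libraries. Their spread was below that estimated by edgeR for the real sites (common dispersion 0.428 for Nfya and 0.275 for Oct4). Recoveries in both tables are therefore upper estimates. Alternatives covered pseudocounts, filters, scaling, a term for the library number, the limma trend, leaving out each library, other list tests, ratio thresholds, separate control libraries, region width, chromosomes and overlap rules.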

Results

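The series measured open chromatin and RNA in mouse preimplantation development. DNase-seq for small inputs, in which DNase I cuts accessible DNA and the fragments are sequenced, was applied to 32 samples, and RNA-seq to 5 samples, 37 in all. Each DNase-seq group had 2 samples. The groups covered 1-cell, 2-cell, 4-cell and 8-cell embryos and morulae, collected 12, 30, 46, 60 and 78 h after fertilization, oocytes from 14-day-old mice, sperm, embryonic stem cells, and maternal and paternal pronuclei isolated at stages PN3 and PN5. Nfya, the DNA-binding subunit of the CCAAT-binding factor NF-Y, was knocked down with siRNA and studied at the 2-cell stage, and the pluripotency transcription factor Oct4 was knocked down and studied at the 8-cell stage, each beside embryos given a control siRNA (siControl). RNA-seq covered 1 sample of 1-cell embryos, 2 of 2-cell siControl embryos and 2 of 2-cell Nfya-KD embryos. DNase I hypersensitive sites (DHSs) came as 1 list per stage, so they have no replicate error, and the embryonic stem cell samples were not analysed here. Positions are on mm9.

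Depth was estimated from the smallest steps of the RPM values in the knockdown tables. By these steps the 2-cell siControl libraries held 2821180 and 14405000 reads and the Nfya-KD libraries 3185710 and 12298700 reads. The 8-cell siControl libraries held 8218430 and 6746370 reads and the Oct4-KD libraries 6692570 and 6918750 reads. For RNA only relative depth was recoverable. Set against 2-cell siControl library 1, the 1-cell library held 0.749 times the reads, siControl library 2 held 0.912 times, Nfya-KD library 1 held 1.02 times and Nfya-KD library 2 held 0.757 times. The RNA libraries numbered 1 stood apart from those numbered 2, with summed FPKM of 243441 and 260569 for siControl 1 and Nfya-KD 1 against 457684 and 449820 for siControl 2 and Nfya-KD 2. Changes within each number are therefore given beside the pooled ones for Nfya, the gene lists that passed and the activated and maternal-high genes. Most other named genes are given per library, and the other lists are given pooled alone. The numbers differed in embryos too, with 10 per RNA library numbered 1, and 16 in siControl 2 and 13 in Nfya-KD 2. Unequal numbers of embryos make these libraries separate pools, but no label says that pools came from separate mothers or fertilizations, so p-values measure only the spread between these samples, which may be technical in part.

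The first comparison asked how the lists of open sites grew with development. The lists held 844 DHSs at the 1-cell stage, 1006 at the 2-cell stage, 2957 at the 4-cell stage, 12323 at the 8-cell stage and 19476 in the morula. Of these, 813, 865, 2475, 7975 and 10674 were at least 200 bp wide, so the rise remained but was smaller. Covered sequence went from 0.281 Mb at the 1-cell stage to 4.40 Mb in the morula. The early sites were mostly promoters by the authors' classes. Promoter-class DHSs made up 736 of 844 sites at the 1-cell stage (87.2%, exact 95% confidence interval 84.8 to 89.4), 77.2% at the 2-cell stage, 74.9% at the 4-cell stage, 51.8% at the 8-cell stage and 48.9% in the morula. Intergenic sites went from 9.60% at the 1-cell stage to 28.7% in the morula, and intronic sites from 2.25% to 17.6%. Intervals here and elsewhere cover counting error only. List size is not a direct count of open sites. Pronuclei at PN5, taken at 12 h like the 1-cell embryos, had 4794 maternal and 2667 paternal sites. Inputs in embryos fell from 100 per library at the 1-cell and 2-cell stages to 50, 25 and 10 at later stages. Later embryos hold more cells each, so input counted in cells did not fall in this way. It was lowest at the 1-cell stage. Depth of the stage libraries was not known, and by the protocol 1-cell embryos received a higher DNase I concentration. Whether these differences shaped the rise or the promoter shares was not tested.

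**Figure D1:**
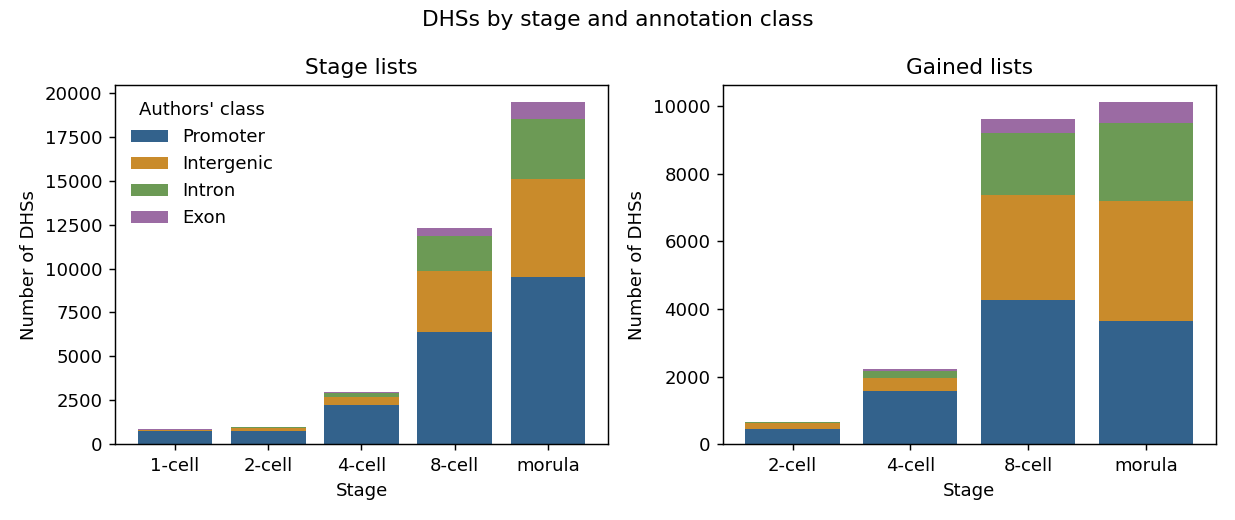
Number of DHSs (vertical axis) per stage (horizontal axis) in the deposited stage lists on the left and the deposited gained lists on the right, coloured by the authors' annotation class. Lists grow from 844 sites at the 1-cell stage to 19476 in the morula, and promoters are 69.3% of the sites gained at the 2-cell stage and 36.0% of those gained in the morula.

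Each deposited gained list was the stage's list minus the list of the stage before, with no exception. There were 671 gained sites at the 2-cell stage, 2216 at the 4-cell stage, 9635 at the 8-cell stage and 10127 in the morula. Gained means absent from the list of the stage before, and not that a site was closed. Of all 1006 2-cell sites 335 were in the 1-cell list, but 716 overlapped a maternal PN5 site. Many gained sites were thus already listed in pronuclei. Promoters made up 69.3% of the 2-cell gained sites and 70.6% of the 4-cell gained sites, a difference that did not pass (odds ratio 0.941, Fisher's exact test, two-sided, adjusted p = 0.53 over 3 tests). With the sites of 2 dense blocks on X left out, a setting chosen after seeing the data, the shares were 77.2% and 70.7%, and the 2-cell share was the higher (odds ratio 1.41, Fisher's exact adjusted p = 0.0015). The share was 44.3% among 8-cell gained sites, lower than at the 4-cell stage (odds ratio 3.01, Fisher's exact adjusted p = 9.37e-112), and 36.0% among morula gained sites, lower again (odds ratio 1.42, Fisher's exact adjusted p = 5.13e-33). These tests take sites as units and hold no replicate of any stage.

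Sites differed in how often they were still listed at the next stage. Of the 1-cell DHSs, 335 of 844 (39.7%) were also listed at the 2-cell stage, against 0.26 on average over 100 shuffles within chromosomes. The shuffles place sites at random along the chromosome, so lists rich in promoters would exceed them in any case. The share was 73.7% from the 2-cell to the 4-cell stage, 90.9% from the 4-cell to the 8-cell stage and 75.9% from the 8-cell stage to the morula. Promoter sites persisted more often than others at each step. From the 1-cell to the 2-cell stage 42.4% of promoter sites (interval 38.8 to 46.1) and 21.3% of the other sites (14.0 to 30.2) were listed again, and from the 8-cell stage to the morula 92.0% (91.3 to 92.6) and 58.5% (57.3 to 59.8). This split by class was chosen after seeing the data. Of the 22621 sites in any of the 5 lists, 9911 were in the morula list alone, 302 were in all 5 lists and 258 were in all but the 2-cell list.

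The pronuclei and gametes show where open sites were shared between the parental genomes. The oocyte list held 866 DHSs and the sperm list 87, of which 59 were on Y and 21 on the mitochondrial genome. Maternal pronuclei had 3948 DHSs at PN3 and 4794 at PN5, and paternal pronuclei 3681 and 2667. Most were narrow, and of at least 200 bp there were 986 and 1651 maternal and 1161 and 874 paternal sites, so the order of maternal and paternal at PN3 depends on width. Many sites were open on both parental genomes. At PN3, 53.4% of maternal sites overlapped a paternal site and 57.1% of paternal sites overlapped a maternal site, and at PN5 the shares were 40.7% and 72.8%. Most oocyte DHSs were found in maternal PN3 pronuclei, 702 of 866 (81.1%), and nearly as many in paternal PN3 pronuclei, 670 (77.4%). At most 4 oocyte DHSs overlapped in any of the 100 shuffles, which set aside only random placement along chromosomes. Later stages also held them, with 32.6% of oocyte DHSs overlapping the 1-cell list (17.8% with 50% reciprocal overlap), 47.5% the 2-cell list and 95.5% the morula list. These shares rose with list size and are not read as sites closing and opening again. Maternal PN5 pronuclei, of the same hour as the 1-cell embryos, held 84.3% of oocyte DHSs. Of the 87 sperm sites 28 overlapped paternal PN3 sites, 25 of them on Y, which maternal pronuclei lack. On autosomes and X 3 overlapped paternal and 3 maternal PN3 sites.

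Sites on X and Y were counted in each pronuclear list. At PN3, 149 of 3948 maternal DHSs (3.77%) and 45 of 3681 paternal DHSs (1.22%) were on X, and at PN5 the shares were 3.86% and 1.46%. Every maternal pronucleus carries an X, while paternal pools mix X-bearing and Y-bearing pronuclei, so a lower paternal share is given by the design and is not read as a difference in accessibility. The Y chromosome had 30 paternal sites at PN3 and 26 at PN5, and no maternal site at either stage.

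The knockdown of Nfya was checked first. Nfya stood at 10.3 and 15.5 FPKM in the siControl libraries (12.9 ± 3.71, SD, n = 2) and at 3.28 and 4.48 FPKM in the Nfya-KD libraries (3.88 ± 0.845, SD, n = 2), with 36.8 FPKM in 1-cell embryos. Its log2 change on the log2(FPKM + 1) scale was -1.50 (SE 0.33), with -1.40 within number 1 and -1.59 within number 2. It did not pass over all genes (limma adjusted p = 1.00). Nfyb, a histone-fold subunit of the same complex, was at 13.0 and 38.8 FPKM in siControl and 52.9 and 127.0 FPKM in Nfya-KD, a log2 change of 1.81 (SE 0.71), and Nfyc, its partner subunit, at 26.6 and 42.5 against 34.5 and 49.5 FPKM.

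Across 10533 genes with at least 1 FPKM in at least 2 libraries, limma with a mean-variance trend called 0 genes lower and 0 higher in Nfya-KD at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 92 lower and 47 higher genes, and the smallest adjusted p was 0.14. Both Nfya-KD libraries lay outside both siControl libraries on one side for 16.9% of genes. Chance would give 33.3% if the 4 libraries were exchangeable, which they are not, since libraries of the same number were closer (r across genes 0.985 and 0.986) than the siControl libraries to each other (0.964). With 1 library left out the count was 31 without siControl 1, 13 without siControl 2, 11 without Nfya-KD 1 and 6 without Nfya-KD 2. Genes simulated to fall by 2 on the log2 scale were recovered in 0% of cases in this comparison, and those falling by 4 in 85.9%. Falls of 2 were therefore not detectable by this fit. The simulation lowered 200 genes above a set expression level together, and adjustment over all genes is stricter where fewer genes change. The 85.9% is thus an upper estimate for a lone gene. Snora28, with a log2 change of -6.31, did not pass (limma adjusted p = 0.14).

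The separated genes of smallest p are given as values, since none passed. The small nucleolar RNA genes Snora28 (106 and 57.8 FPKM) and Snora70 (28.8 and 63.2 FPKM) and the defensin gene Defb40 (3.59 and 5.91 FPKM) were listed at 0 in both Nfya-KD libraries. No read counts were at hand, so the number of reads behind the values of small RNA genes is not known. Gm9 was at 32.1 and 49.4 FPKM in siControl and at 0.476 and 0.0801 FPKM in Nfya-KD. Hes1, a Notch target and transcriptional repressor, was at 18.9 and 43.0 against 3.27 and 1.31 FPKM, a log2 change of -3.24 (SE 0.53). Elf3, an epithelial transcription factor of the ETS family, was at 20.2 and 22.3 against 5.47 and 4.14 FPKM. Cd74, the MHC class II invariant chain, was at 8.85 and 11.2 against 2.25 and 1.73 FPKM, and the tetraspanin gene Tspan31 at 26.5 and 37.3 against 6.68 and 7.68 FPKM. The others of this kind were 2810417H13Rik, with a log2 change of -1.58, and 2610318N02Rik, with -1.80.

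On the higher side Gm9846 was at 0.881 and 1.64 FPKM in siControl and at 73.0 and 154 FPKM in Nfya-KD, a log2 change of 5.59 (SE 0.47). Nudt2, a hydrolase of diadenosine tetraphosphate, was at 2.63 and 6.07 against 13.4 and 18.7 FPKM. Tm2d1 was at 3.13 and 4.61 against 8.59 and 12.7 FPKM, and Mrps10, a mitochondrial ribosomal protein gene, at 2.197 and 0.644 against 4.47 and 6.49 FPKM. The remaining 6 were 1700080O16Rik (log2 change 1.62), 2510003D18Rik (1.20), 0610040B10Rik (1.10), 2310004N24Rik (1.07), C130060C02Rik (1.00) and 2410076I21Rik (0.87). Some genes with names of the Gm and Rik kind have near-identical copies, and their FPKM values are uncertain to that extent.

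**Figure D2:**
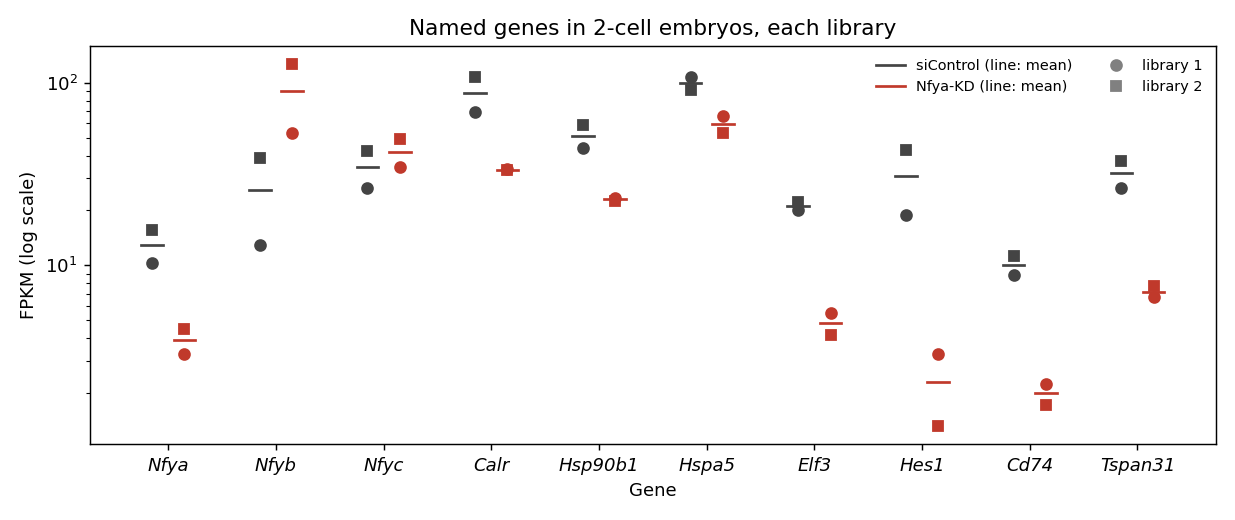
FPKM on a log axis (vertical) of 10 genes (horizontal) in 2-cell embryos, with circles for the libraries numbered 1, squares for those numbered 2 and lines for the mean of 2 libraries, siControl in grey and Nfya-KD in red. Nfya lies at 10.3 and 15.5 FPKM in siControl and at 3.28 and 4.48 FPKM in Nfya-KD, and Calr at 68.9 and 107.9 against 33.7 and 33.4 FPKM.

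Of the fixed gene lists, 3 passed camera with a preset correlation. Genes of the unfolded protein response were lower in Nfya-KD, with 12 of 18 measured members under 0, a mean log2 change of -0.25 and medians of -0.16 within number 1 and -0.10 within number 2 (camera adjusted p = 0.039, and adjusted p = 0.97 with an estimated correlation). Among its members, none of which passed singly, the chaperone gene Calr was at 68.9 and 107.9 FPKM in siControl and 33.7 and 33.4 FPKM in Nfya-KD, a log2 change of -1.34 (SE 0.43), Hsp90b1 at 43.9 and 59.0 against 23.5 and 22.5 FPKM, a log2 change of -1.12 (SE 0.37), Hspa5 at 107.9 and 91.1 against 65.6 and 53.05 FPKM, and Dnajb9 at 121 and 322 against 106 and 224 FPKM. Ribosomal protein genes were higher, with 69 of 77 over 0, a mean of 0.19, and medians of 0.27 and 0.06 within numbers 1 and 2 (camera adjusted p = 0.043, and adjusted p = 0.97 with an estimated correlation). The ribosomal RNA precursor gene Rn45s stood at 6007 and 1315 FPKM in siControl and 4232 and 1179 FPKM in Nfya-KD. Among the ribosomal protein genes Rpl41 was at 1228 and 6121 against 1489 and 5758 FPKM, Rplp2 at 752 and 2242 against 867 and 2413, Rpl26 at 2.46 and 7.26 against 9.71 and 12.0, and Rpl36 at 38.7 and 60.6 against 61.4 and 87.0 FPKM. Genes of the 2-cell stage were lower, with 30 of 40 under 0 and a mean of -0.18 (camera adjusted p = 0.044, and adjusted p = 0.97 with an estimated correlation), but the median was 0.08 within number 1 and -0.46 within number 2. Sp110 was at 256 and 1046 against 291 and 999 FPKM, Gm4340 at 264 and 817 against 217 and 469, Zscan4b at 4.87 and 7.53 against 4.67 and 3.54, and Zscan4e at 4.16 and 6.03 against 3.43 and 3.60 FPKM. Members of multigene families such as Zscan4b and Zscan4e are uncertain, since reads can be split between copies. Fry called 0 of these lists. Without siControl 2 the mean of the 2-cell-stage genes was 0.41, without Nfya-KD 1 it was 0.15, and the mean of the ribosomal protein genes was -0.39 without siControl 1 and -0.27 without Nfya-KD 2. The mean of the unfolded protein response was -0.33 without siControl 1, -0.22 without siControl 2, -0.20 without Nfya-KD 1 and -0.30 without Nfya-KD 2.

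**Figure D3:**
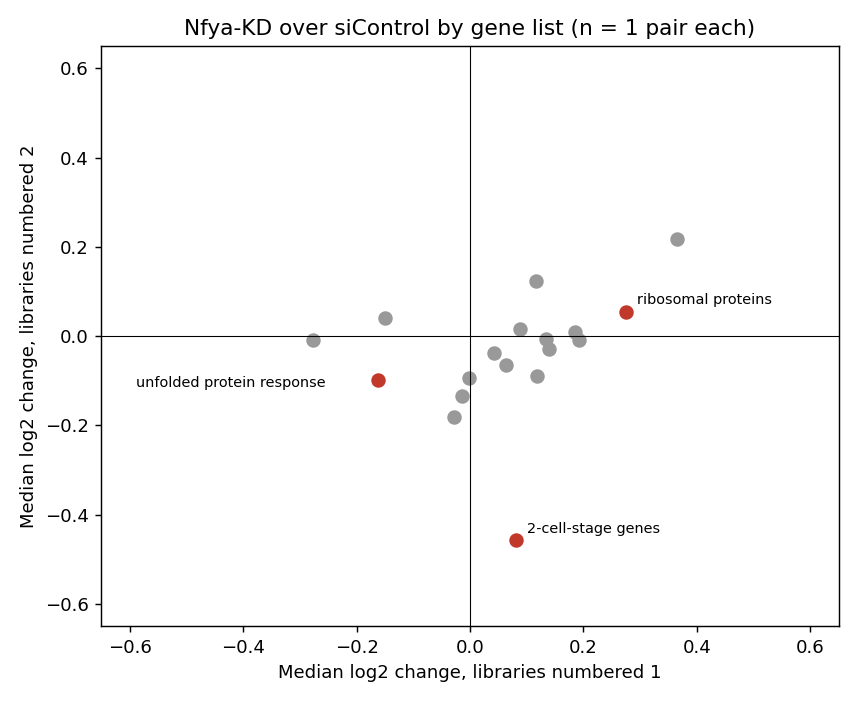
Median log2 change of Nfya-KD over siControl for 18 fixed gene lists, within the libraries numbered 1 (horizontal) and numbered 2 (vertical), 1 pair of libraries each, with the 3 lists that passed camera with a preset correlation in red and named. The 2-cell-stage genes lie at 0.08 and -0.46, the unfolded protein response at -0.16 and -0.10, and the ribosomal protein genes at 0.27 and 0.06.

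The other 15 tested lists did not pass in this fit, which has no term for the library number. Maternal oocyte genes had 36 of 48 members over 0 and a median of 0.11 (camera adjusted p = 0.064), with Omt2b at 5668 and 15606 FPKM in siControl and 6895 and 15063 FPKM in Nfya-KD, Omt2a at 5334 and 15411 against 6486 and 14621, Mos at 1.42 and 1.95 against 2.90 and 2.92, and Zar1 at 8.74 and 10.4 against 10.1 and 20.1 FPKM. NF-Y-dependent cell cycle genes had 18 of 24 under 0 and a median of -0.13 (camera adjusted p = 0.14), with cyclin B1, Ccnb1, at 262 and 846 against 257 and 742 FPKM. The remaining lists had camera adjusted p-values from 0.53 to 0.93. Their median log2 changes were 0.07 for 21 heat shock protein genes, 0.03 for 49 ribosome biogenesis genes, 0.05 for 37 translation initiation genes, 0.02 for 43 splicing genes, 0.10 for 34 proteasome genes, -0.02 for 36 genes of mRNA processing and export, 0.07 for 38 transcription machinery genes and 0.01 for 37 chromatin regulators. They were -0.06 for 23 pluripotency and lineage factors, -0.11 for 13 p53 response genes, -0.13 for 8 interferon response genes and 0.05 for 4 sperm and testis genes. Median, mean and test differed in sign for several lists. Camera gave the direction as down for the NF-Y subunits (median 0.29, mean 0.20), for ribosome biogenesis (mean 0.0050), for heat shock proteins (mean -0.00092) and for sperm and testis genes (mean -0.056), and as up for mRNA processing and export (mean 0.0045). No member of any list passed over all genes, and adjusted over the list alone 1 of 3 NF-Y subunits passed and 0 members of the other lists.

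The most abundant member of each of these lists is given per library. Snrpg was at 1114 and 3335 FPKM in siControl and 1418 and 3335 FPKM in Nfya-KD, Eif1 at 729 and 1937 against 835 and 1958, Polr2j at 473 and 1375 against 518 and 1655, Npm1 at 389 and 536 against 485 and 503, and Pabpn1 at 224 and 666 against 226 and 529 FPKM. Suz12 was at 200 and 160 against 217 and 157, Hsp90aa1 at 117 and 236 against 144 and 210, Psmb1 at 83.4 and 232 against 116 and 256, and Klf17 at 85.6 and 96.4 against 89.1 and 81.1 FPKM. Gadd45a was at 25.0 and 45.3 against 17.9 and 29.7, Ifi35 at 21.2 and 56.8 against 17.5 and 45.2, and Ldhc at 3.88 and 7.42 against 4.56 and 7.62 FPKM. Only 2 of 18 cumulus and granulosa cell markers were measured, too few to test, with Tnfaip6 at 4.78 and 5.17 against 4.32 and 2.51 FPKM and Vim at 3.49 and 1.19 against 1.54 and 1.25 FPKM. The sperm gene Prm2 was at 2.98 and 6.53 against 1.84 and 9.33 FPKM.

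Genes higher in 2-cell siControl than in 1-cell embryos, here called activated, were then followed in Nfya-KD. The name stands for an FPKM ratio over 1 library, and new transcription was not measured. The 942 tested genes that were at least 5-fold higher in 2-cell siControl than in 1-cell embryos had a median log2 change of -0.04 and a mean of -0.12, with 518 under 0 and 424 over 0 (camera adjusted p = 0.0022, and adjusted p = 0.69 with an estimated correlation). The median was 0.08 within number 1 and -0.18 within number 2, so the direction did not hold within numbers. The 718 tested genes that were at least 5-fold lower at the 2-cell stage had a median of 0.11, with 489 over 0 and 229 under 0 (camera adjusted p = 6.08e-05, and adjusted p = 0.042 with an estimated correlation), and medians of 0.08 and 0.12 within numbers 1 and 2. Both sets were chosen on these siControl libraries, so neither is independent evidence of its direction. With the maternal-high set defined by siControl 2 its median within number 1 was 0.04, no higher than the 0.04 of all genes, and with the set defined by siControl 1 it was 0.10 within number 2, against -0.02 for all genes. With both Nfya-KD libraries measured against the siControl library not used to define the set, its medians were -0.00072 and -0.04. Against the same siControl library that defined it, they were 0.19 for siControl 2 and 0.20 for siControl 1. In these fits the sign thus followed whether the defining library was used again. The median of the activated genes was 0.29 without siControl 2 and 0.30 without Nfya-KD 1. That of the maternal-high genes was 0.13 without Nfya-KD 1 and ran from 0.08 to 0.20 with 1 library left out.

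The 1-cell and 2-cell siControl embryos differed widely in RNA. The 1-cell stage had 1 library, so there is no replicate check and no p-value. The highest ratios on the (FPKM + 1) scale belonged to Dcdc2c, at 3.99 FPKM in 1-cell embryos and 2833 and 3630 FPKM in 2-cell siControl, and to Gm4850, at 0.167 against 353 and 1036 FPKM. Also among the 10 highest were the homeobox genes Obox3 (0.506 against 124 and 1147 FPKM), Obox6 (0.0522 against 148 and 408 FPKM) and Crxos1 (0.514 against 177 and 1008 FPKM), with Mt1, a metallothionein gene, at 4.29 against 494 and 2899 FPKM. Gm7102 went with them at 3.24 against 1638 and 2366 FPKM, as did Gm11517 at 0.250 against 146 and 1202 and B020004C17Rik at 0.135 against 164 and 583 FPKM. Snora30 was listed at 0 in 1-cell embryos and at 309 and 678 FPKM in 2-cell siControl. In the other direction Gm813 was at 441 FPKM in 1-cell embryos and 4.95 and 3.25 FPKM in siControl, Pabpn1l, an oocyte poly(A)-binding protein gene, at 131 against 1.32 and 2.84, Rgs2 at 374 against 8.29 and 16.1, Zfp57, a zinc finger regulator of imprinting, at 1095 against 31.1 and 50.1, A430033K04Rik at 217 against 6.00 and 7.80, and Bms1 at 247 against 9.92 and 8.12 FPKM. The microRNA genes Mir31, Mir423, Mir1983 and Mir546 were at 507, 288, 31.8 and 26.4 FPKM in 1-cell embryos and listed at 0 in both siControl libraries. How many reads lie behind the values of these genes and of Snora30 is not known.

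As groups, 34 of 40 genes of the 2-cell-stage list were at least 5-fold higher at the 2-cell stage, with a median log2 ratio of 5.02, above all 10000 random lists matched on expression (percentile 100). Of 48 maternal oocyte genes 22 were at least 5-fold lower, with a median of -2.20 (percentile 0). Ribosomal protein genes had a median of 2.43 (percentile 100), with 40 of 76 at least 5-fold higher. These percentiles describe these libraries alone.

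Knockdown of Nfya was linked to open chromatin through the authors' list of 2-cell DHSs with lower DNase signal. It held 286 of the 1006 2-cell DHSs (28.4%, exact 95% confidence interval 25.7 to 31.3). Promoters made up 84.6% of the decreased and 74.3% of the other sites (odds ratio 1.90, Fisher's exact test, two-sided, adjusted p = 0.0016 over 5 tests), a test chosen after seeing the data. The decreased sites were less often 2-cell gained sites, 60.5% against 69.2% (odds ratio 0.682, Fisher's exact adjusted p = 0.012), and 113 of the 335 sites also in the 1-cell list were among them. They were more often listed again at the 4-cell stage, 81.1% against 70.7% (odds ratio 1.78, Fisher's exact adjusted p = 0.0016), the 8-cell stage, 96.2% against 92.6% (Fisher's exact adjusted p = 0.044), and in the morula, 95.5% against 90.1% (Fisher's exact adjusted p = 0.0087). With the sites of 2 dense blocks on X left out, a setting chosen after seeing the data, only the 4-cell difference passed (odds ratio 1.65, Fisher's exact adjusted p = 0.031 over 5 tests). Those in promoters (87.1% against 81.2%), in 2-cell gained sites, at the 8-cell stage and in the morula did not (Fisher's exact adjusted p = 0.073, 0.074, 0.21 and 0.21). Their odds ratios were 1.56, 0.742, 1.73 and 1.57, on the same side of 1 as with the blocks. These tests take sites as units of a list that rests on 2 libraries per group. Their p-values describe association among listed sites and do not measure an effect of Nfya loss. Whether decreased and other sites differed in signal strength was not tested.

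Signal in the decreased 2-cell sites differed between the numbers, with 70 embryos in each library numbered 1 and 90 in each numbered 2. In the authors' deposited table the log2 fold of siControl over Nfya-KD ran from 1.00 to 3.58 with a median of 1.44. Summed over the 286 sites, RPM was 5.05-fold higher in siControl 1 than in Nfya-KD 1 and 1.67-fold higher in siControl 2 than in Nfya-KD 2, with log2 fold medians of 2.18 and 0.62. Within number 1 alone 264 of the sites had a log2 fold above 1, and within number 2 alone 92. Mean RPM was 1.95 and 0.639 in siControl 1 and 2 and 0.386 and 0.383 in Nfya-KD 1 and 2, so at these sites the numbers differed mostly in siControl. The sites were selected on these same values, and values of the other 2-cell sites were not at hand. This is therefore not read as a property of the libraries. A site had a median of 5 and 8 reads in siControl libraries 1 and 2 and of 1 and 4 reads in Nfya-KD libraries 1 and 2, and 108 sites had no read in Nfya-KD library 1. Both Nfya-KD values lay under both siControl values at 164 of 286 sites (57.3%, where chance gives 16.7% for exchangeable libraries), but the sites were selected for this fall on these same libraries. No site passed singly, with 0 calls by limma on log2(RPM + 0.1) (11 at an unadjusted p under 0.05) and 0 by edgeR on the recovered reads (8 at an unadjusted p under 0.05). As an example chosen after its values were seen, the promoter-class site on chromosome 7 from 3596421 to 3596750 had 7.44 and 1.53 RPM in siControl and 0.314 and 0.488 RPM in Nfya-KD, and the promoter-class site on chromosome 19 from 12039801 to 12040250 had 6.38 and 1.11 against 0.314 and 0.407 RPM.

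Oct4 knockdown was set against the sites gained at the 8-cell stage. The authors' decreased list held 2643 of the 9635 8-cell gained DHSs (27.4%, exact 95% confidence interval 26.5 to 28.3). These were less often promoters, 36.7% against 47.2% of the other gained sites (odds ratio 0.649, Fisher's exact test, two-sided, adjusted p = 3.05e-20 over 2 tests, chosen after seeing the data), and less often listed in the morula, 62.7% against 72.5% (odds ratio 0.638, Fisher's exact adjusted p = 3.05e-20). By class, 22.7% of promoter, 30.8% of intergenic, 32.2% of intronic and 29.8% of exonic gained sites were decreased. As for Nfya, sites are the units here and the list rests on 2 libraries per group. The p-values therefore do not measure an effect of Oct4 loss, and a part of site strength in these differences was not tested. In the authors' deposited table the log2 fold of siControl over Oct4-KD ran from 1.00 to 6.86 with a median of 1.56. At 262 sites both Oct4-KD libraries were at 0, where the fold depends on the 0.01 added to RPM, and the largest fold at any other site was 3.84. Summed RPM was 4.45-fold higher in siControl 1 than in Oct4-KD 1 and 1.85-fold higher in siControl 2 than in Oct4-KD 2, and 2347 sites had a log2 fold above 1 within number 1 and 1173 within number 2. Mean RPM was 1.05 and 0.518 in siControl 1 and 2 and 0.237 and 0.280 in Oct4-KD 1 and 2. Both Oct4-KD values lay under both siControl values at 1637 of 2643 sites (61.9%, where chance gives 16.7% for exchangeable libraries), again among sites selected on these libraries. Limma called 0 of these sites (244 at an unadjusted p under 0.05) and edgeR on the recovered reads 0 (210 at an unadjusted p under 0.05). Sites simulated to fall 4-fold at this depth, with less spread than the real sites, were recovered in 0% of cases by limma and 1% by edgeR. As examples chosen after their values were seen, the promoter-class site on chromosome 9 from 110558861 to 110559030 had 3.41 and 3.11 RPM in siControl and 1.35 and 0.578 RPM in Oct4-KD, and the intronic site on chromosome 12 from 31607361 to 31607550 had 3.04 and 3.41 against 1.49 and 1.16 RPM. With 0.1 added to RPM in place of 0.01, a setting chosen after seeing the data, 1997 of the 2643 sites had a log2 fold above 1. The tests of class and of presence in the morula were not repeated on these 1997 sites. The Nfya list was made with 0.1 added, so its tests and those of the Oct4 list are not directly comparable.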

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

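The settings that leave out small nucleolar RNA genes or the dense X blocks, split sites by class, change the value added to RPM, measure sets within 1 number or use edgeR were chosen after seeing the data. Of 200 alternative values 120 kept their direction and side of the threshold, or stayed within the limits set for counts and shares. Part of these could not have changed. Stage, gained and decreased lists share coordinates, so the overlap rules return the same values among them, and merging found no overlapping regions within a list. A smaller value added to RPM can only raise the Nfya fold. The tally is therefore no measure of robustness. The cause of the others was not tested except where given.

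The count of genes changed in Nfya-KD, 0 with the planned settings, was 1 with pseudocount 0.1, 3 with quantile normalization, 3 with median scaling and 0 under every other filter, trend or pseudocount setting, and ran from 6 to 31 with 1 library left out, where the lone library is assumed to vary like the other group. With the library number as replicate block it was 11. The numbers are not said to pair the samples. Deviations from the group means of siControl 1 and Nfya-KD 1 correlated at 0.744 across genes, and with 2 pairs this was not used as pairing. In simulation the blocked fit gave more false calls than its threshold allows. Nfya's log2 change ran from -1.77 to -1.22 with 1 library left out and passed in no setting.

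Of the fixed lists 3 passed with the planned settings, 5 with quantile normalization, 4 with median scaling, 5 with the replicate block, 0 with an estimated correlation, 0 with fry and from 1 to 9 with 1 library left out. The replicate block added the maternal oocyte genes (camera adjusted p = 0.0011) and the NF-Y-dependent cell cycle genes (camera adjusted p = 0.025) to the planned 3. The means ran from -0.78 to 0.41 for the 2-cell-stage genes, from -0.39 to 0.76 for the ribosomal proteins and from -0.33 to -0.20 for the unfolded protein response with 1 library left out. They turned sign without siControl 2 (0.41) and Nfya-KD 1 (0.15) for the 2-cell-stage genes and without siControl 1 (-0.39) and Nfya-KD 2 (-0.27) for the ribosomal proteins. Such a fit sets libraries of unequal numbers against each other.

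The median of the activated genes ran from -0.61 to 0.30 with 1 library left out, turning sign without siControl 2 (0.29) and Nfya-KD 1 (0.30). With siControl 2 defining the set it was 0.51 against siControl 1 and 0.11 within number 1, and with siControl 1 defining it -0.45 against siControl 2 and -0.18 within number 2. The median of the maternal-high genes ran from 0.077 to 0.20 with 1 library left out, was -0.00072 with siControl 1 defining and siControl 2 measuring, -0.044 the other way, and 0.039 within number 1 with siControl 2 defining.

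Keeping regions of at least 200 bp left 7975 8-cell, 10674 morula, 12 sperm, 242 oocyte, 986 maternal PN3, 1161 paternal PN3, 1651 maternal PN5 and 874 paternal PN5 DHSs, and autosomes and X alone left 7 sperm DHSs. With 50% reciprocal overlap 17.8% of oocyte DHSs were in the 1-cell list, 47.2% of maternal PN3 in paternal PN3, 50.6% the other way, 37.5% of maternal PN5 in paternal PN5, 67.4% the other way, 15.1% of maternal PN3 and 15.4% of paternal PN3 in the oocyte list, and 9.45% of maternal PN5 and 13.2% of paternal PN5 in the 1-cell list. Shares listed again at the next stage were 21.3% for other classes from the 1-cell stage, 83.9% for promoters and 38.9% for other classes from the 2-cell stage, 95.4% and 77.6% from the 4-cell stage, and 92.0% and 58.5% from the 8-cell stage. With the dense X blocks left out 3.63% of 2-cell DHSs were on X, the odds ratio of promoters in 2-cell against 4-cell gained sites turned to 1.41, since all sites removed from the 2-cell list were intergenic, and that of 2-cell gained among Nfya-KD decreased sites was 0.742 and did not pass. With 0.1 added to RPM 20.7% of 8-cell gained sites counted as decreased in Oct4-KD.

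Lists limited to their strongest sites were not run, since the lists carry no score, nor were distances to genes. The region tests had few reads per site and 2 libraries per group, and the parts of these in the lack of calls were not separated. The 1-cell RNA has no replicate.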

Other observations

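The tests of repeated copies at the X blocks, of the sensitivity of the 2-cell list and of the number 2 libraries alone were chosen only after the result was seen, as were the blocks themselves.

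The 2-cell list held 103 DHSs on X, 10.2% of its sites, against 3.67% at the 1-cell stage and 3.75% at the 4-cell stage. Much of this lay in 2 dense blocks, 39 sites from 4123081 to 4894490 and 30 sites from 31534561 to 32178830 on X (mm9), where neighbouring sites were at most 500 kb apart. All 69 were intergenic by the authors' class and all were gained at the 2-cell stage. The same rule gave 4 more blocks in the 2-cell list, on chromosomes 8, 9 and 10, mostly of promoters, and on Y. The X blocks held 21 sites at the 4-cell stage, 61 at the 8-cell stage and 43 in the morula, and 0 in the 1-cell, oocyte, sperm and all 4 pronuclear lists. Leaving them out put 3.63% of 2-cell DHSs on X.

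Reads from repeated copies counted at the blocks in every library would also give sites at the 1-cell stage and in maternal pronuclei, where the most found in any list was 0. A copy number difference of the JF1 paternal strain may contribute, since the labels' protocol gives JF1 sperm for the 2-cell embryos and BDF1 sperm for the 1-cell embryos, whose strain label names JF1. Of 8 block sites in the Nfya table, whose embryos are labelled with BDF1 parents, all had 2 to 9 reads in siControl 2 and 5 had reads in siControl 1, where no reads were predicted, but 1 alone had 3 or more reads in each siControl library, and sites enter that table only if siControl has signal, so this stays open. The 10 block sites of the Oct4 table, also labelled BDF1, had 0 to 4 and 0 to 5 reads in siControl 1 and 2 and 0 had 3 or more in each, which leaves it open too. Opening of these blocks with the start of embryonic transcription stays an untested explanation.

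Of the 844 1-cell DHSs, 509 were missing from the 2-cell list, and 485 of these (95.3%) were listed at a later stage. Among sites listed both before and after a stage, 46.6% were missing at the 2-cell stage, 22.0% at the 4-cell stage and 5.98% at the 8-cell stage. Stronger DNase digestion of the 1-cell embryos as the whole cause goes against the pronuclei, made with the lower amount, since 83.1% of the missing sites overlapped a pronuclear site, although 97.0% of the sites kept at the 2-cell stage did, so a part in it stays open. Lower sensitivity of the 2-cell list may account for part of it. Of 352 1-cell sites open in the 4-cell, 8-cell, morula and all 4 pronuclear lists, 33.8% (interval 28.9 to 39.0) were missing at the 2-cell stage, a share that leaves sensitivity and closing at the 2-cell stage open.

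The 2-cell-stage genes had a pooled mean under 0 in Nfya-KD and the maternal oocyte genes, which did not pass, one over 0, and a profile closer to the 1-cell stage could give both. That would need the activated genes to be lower in both numbers, and with the set defined by the other number's control their median was 0.11 within number 1 (interval over genes 0.09 to 0.13, with 0.04 for all genes), although it was -0.18 within number 2. Chance values of shared control libraries may add to the pooled values, since with separate control libraries the correlation across genes between the knockdown and 2-cell over 1-cell changes was 0.040 in number 1, where the 2-cell-stage genes were not lower. In number 2 it was -0.16 without any shared library, so shared controls are not the cause there. An effect of Nfya loss in number 2 alone stays open and untested, since each number is 1 pair of libraries and genes are not independent replicates.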
